A study of Homo sapiens with 16 samples.

How the data were processed

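CUT&RUN, which releases fragments around an antibody target with a protein A/G-micrococcal nuclease fusion, was run on LNCaP cells with antibodies against EZH2, H3K4me3, H3K27me3 and an IgG control, per the labels. The 16 samples form 4 conditions, the guides sgControl (called sgC here) and sgPRKCI each with DMSO or 10 µM enzalutamide for 72 h, with 1 library per antibody and condition. Peak lists of 12 libraries were used, and the 4 IgG libraries are not analysed here. Groups were taken from the genotype, treatment and antibody labels. The protocol adds a nucleosome spike-in, whose reads are not used here.

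FastQC, Trimmomatic, Bowtie2, SAMtools and MACS2 and the genome build GRCh38 are named in the submitters' processing notes, without versions or parameters. Per the files' layout the authors deposited MACS2 narrow peaks for EZH2 and H3K4me3 and broad peaks for H3K27me3, called for each library alone. Each deposited peak carries a fold enrichment ratio over the caller's local background, a −log10 p and a −log10 q, and a score that is 10 times the −log10 q; these are the authors' values and were used to describe, rank or filter peaks within a list. Fold enrichments set side by side for several libraries describe each list and are not on a common scale; heights compared between libraries are the recovered ones described below. Column 10 of the narrow lists, as deposited, gives the offset of the summit in bp. The lowest −log10 q was between 4.00 and 4.05 in the 8 narrow lists and between 1.00 and 1.02 in the broad lists, which sets the threshold behind every count. Peak calling depends on depth, so a missing peak means that none passed that threshold.

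Total read numbers are not given in the sources used here. The summit pileup and the local background were recovered from the fold enrichment and −log10 p of each narrow peak, since the caller derives both from them; whole fragments were found, to within 0.002 in −log10 p, for 100.0% of peaks in 7 lists. The EZH2 library of sgPRKCI enzalutamide gave whole fragments for 99.9% of peaks once a scaling of its pileup by 0.890 was allowed. The lowest local background, divided by that scale, is the mean fragment coverage of a library over the caller's genome size and served as its depth; a summit height is its pileup over that coverage. Broad peaks hold region means, so the depth of the H3K27me3 libraries is unknown. Simulated peaks were made with the caller's formula and solved at their true scale. Among 1977 unscaled and 1961 scaled peaks, those that were solved had the right number of fragments in 100.0% of cases. The search for a scale, used for sgPRKCI enzalutamide, was not simulated.

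Peaks on chromosomes 1 to 22, X and Y were used; other contigs held between 2.39% and 6.50% of a list, and 1 row with a malformed contig name was left out with them. An EZH2 peak was placed in a class by an overlap of at least 1 bp with the H3K4me3 and H3K27me3 peaks of its own condition, beside 100 random placements. Gene positions came from the RefSeq table of the same build, with 20037 protein-coding genes. That table gives no strand, so a transcription start could not be placed, and a gene counted as having a peak where one lay within 1 kb of either annotated end. With the H3K4me3 libraries pooled, 10996 of these genes had the mark at a single end, 1603 at both and 7438 at neither. A gene was gained where the second library had a peak within 1 kb and the reference library none within 5 kb of either end, and lost in the reverse case. On simulated peaks all 96 planted changes were called.

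The members of 16 gene lists, all of whose names matched (aliases counted as the same gene), were counted per library. Each count was set beside 10000 random lists of the same size, matched on the number of H3K4me3 libraries with a peak at the gene (0, 1 to 3 or 4) for EZH2 and H3K27me3; the percentile describes these libraries and is no test. Of 200 simulated random lists, 5.00% fell outside the central 95%. With 1 library per condition there is no test across conditions. Peaks and genes are not independent, so the binomial intervals are too narrow for any wider claim. Named genes were the 8 gained and 8 lost per EZH2 comparison with the highest −log10 q, the 5 in each direction for H3K4me3, the 5 in each direction for H3K27me3 with no peak within 5 kb of either end in one library and at least 5 kb of the 10 kb around an end covered in the other, up to 4 members per list with the highest EZH2 −log10 q or, among members without a peak, in alphabetical order, and PRKCI and EZH2 among the genes fixed by name. BMI1, MAF, ACP3, KLK2 and KLK3 are named as members of their lists by that rule. Lists, comparisons, alternatives and this rule were fixed before the data were examined, except the use of both gene ends and the alternatives that the closing part names as chosen later.

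Alternatives covered a stricter q, equal numbers of peaks, the overlap required, the marks used, merging of nearby peaks, the window, the margin for gained and lost genes, other contigs and unmatched random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.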

Results

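EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), was profiled by CUT&RUN in LNCaP cells, an established androgen-responsive prostate carcinoma line, together with H3K4me3, a mark of active promoters, and H3K27me3, the mark that PRC2 deposits. Cells carried either a control guide (sgC) or a guide against PRKCI (sgPRKCI), the gene of the atypical protein kinase C iota, and received DMSO or 10 µM enzalutamide, an antiandrogen, for 72 h. Each antibody gave 1 library in each of the 4 conditions, so the 12 peak lists carry no replicate spread and no difference below has a replicate check. Intervals are exact 95% binomial intervals on shares and cover counting error only. On chromosomes 1 to 22, X and Y the EZH2 libraries held 11452 peaks in sgC DMSO, 6182 in sgPRKCI DMSO, 15373 in sgC enzalutamide and 24551 in sgPRKCI enzalutamide. The H3K4me3 libraries held 17424, 18967, 19294 and 18926 peaks in the same order, and the H3K27me3 libraries 100414, 98353, 98809 and 78855. Genome-wide fragment coverage, recovered from the peak values, was 1.35, 1.13, 1.68 and 1.53 for EZH2 and 0.842, 1.22, 1.56 and 1.39 for H3K4me3 in that order.

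PRKCI itself, on chromosome 3, carried an H3K4me3 peak at an annotated end in all 4 conditions, with fold enrichments of 27.9 to 49.4 within the separate lists, and no H3K27me3 peak in any. A promoter mark does not report on an edited coding sequence, so the PRKCI values do not check the genotype labels. An EZH2 peak lay at PRKCI in sgPRKCI enzalutamide alone, from 170221891 to 170223542, with a fold enrichment of 27.4. The EZH2 gene on chromosome 7 also had H3K4me3 peaks and lacked H3K27me3 peaks in all 4 conditions. An EZH2 peak was called at this gene in sgC DMSO, with a fold enrichment of 3.86, and in sgPRKCI enzalutamide, with a fold enrichment of 35.9. The sgPRKCI enzalutamide library had EZH2 peaks at 95.8% of genes with H3K4me3. Its calls at PRKCI and EZH2 are thus not particular to these genes and may come from H3K4me3 fragments, as described below.

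The title of the series names a non-canonical EZH2 cistrome, and the first question was where EZH2 lay relative to the PRC2 product and to active promoters. EZH2 peaks with H3K27me3 made up 71.7% (70.9 to 72.5) of the sgC DMSO list, 86.4% (85.5 to 87.2) of sgPRKCI DMSO, 92.8% (92.4 to 93.2) of sgC enzalutamide and 43.9% (43.3 to 44.5) of sgPRKCI enzalutamide. EZH2 peaks with H3K4me3 and without H3K27me3 made up 23.8% (23.1 to 24.6), 11.5% (10.7 to 12.3), 4.39% (4.07 to 4.73) and 55.4% (54.8 to 56.1) in the same order. In 100 random placements of the same peaks on their own chromosomes, the mean share at H3K4me3 without H3K27me3 was 1.59%, 1.78%, 1.81% and 2.04%, and the mean share at H3K27me3 was 10.0%, 11.6%, 13.8% and 11.3%. The number of EZH2 peaks in the H3K4me3 class was 2730 in sgC DMSO, 712 in sgPRKCI DMSO, 675 in sgC enzalutamide and 13610 in sgPRKCI enzalutamide. The class is set by the marks and not by distance to a gene. In sgPRKCI enzalutamide, 11591 EZH2 peaks of any class lay within 1 kb of an annotated end of a protein-coding gene. In the first 3 libraries the peaks of the H3K4me3 class had median fold enrichments of 5.39, 5.69 and 4.82 and median widths of 414, 348.5 and 451 bp. Their median recovered heights were 15.9, 16.9 and 13.1, where H3K27me3 peaks without H3K4me3 had heights of 12.6, 15.1 and 10.7. In sgPRKCI enzalutamide the H3K4me3 class had a median fold enrichment of 18.7 and a median width of 1309 bp. The H3K27me3 peaks without H3K4me3 of that library had a median fold enrichment of 6.83 and a median width of 422.5 bp. Peaks outside every H3K4me3 peak of the 4 conditions numbered 7717, 4784, 13704 and 10023, and 94.3%, 97.6%, 97.0% and 99.0% of them lay at H3K27me3.

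**Figure D1:**
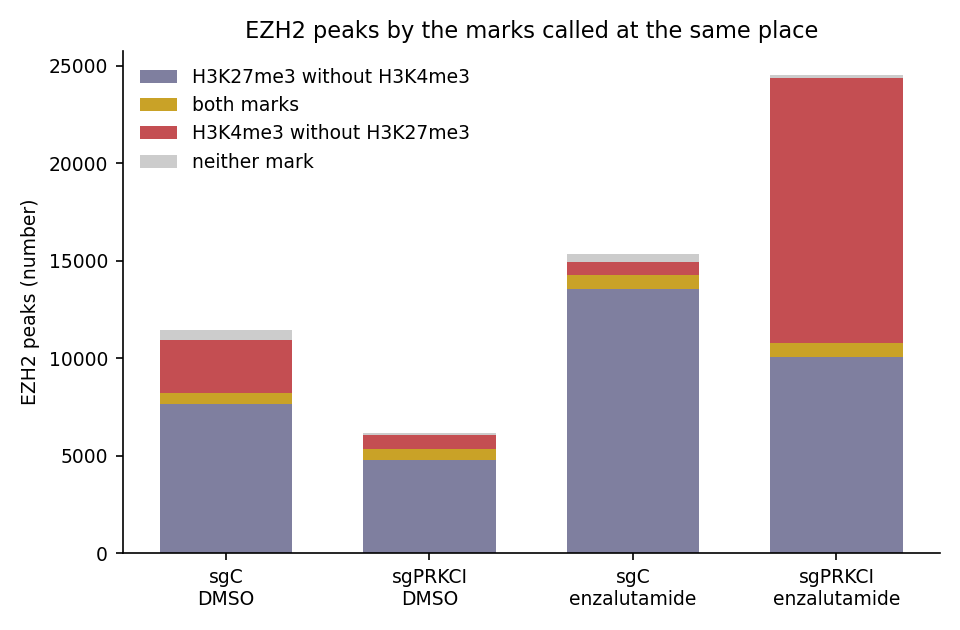
Number of EZH2 peaks (vertical axis) in each of the 4 conditions (horizontal axis), split by the marks called at the same place in the same condition; each bar is 1 library. The H3K4me3 class without H3K27me3 holds 13610 peaks in sgPRKCI enzalutamide and 675 in sgC enzalutamide.

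The first comparison set sgPRKCI against sgC in DMSO and asked what the PRKCI guide did to EZH2 in untreated cells. EZH2 lay within 1 kb of an annotated end of 3657 protein-coding genes in sgC and of 1537 in sgPRKCI, 18.3% (17.7 to 18.8) and 7.67% (7.31 to 8.05) of 20037 genes. Of these, 2165 genes lost and 133 gained EZH2, a gain or loss requiring no peak within 5 kb of either end in the other library. H3K4me3 marked 1929 of the 2165 lost genes in sgC. The lost genes with the highest −log10 q were SH3GLB1, FGFR3, PPM1L, MSRA, TWIST1, SEMA5A, CAMK2N2 and TMEM19. FGFR3 encodes a fibroblast growth factor receptor, and its sgC peak on chromosome 4, from 1793340 to 1795364, had a fold enrichment of 14.9; H3K27me3 was called at an end of the gene in sgC and not in sgPRKCI in DMSO. TWIST1, a transcription factor of mesenchymal development, lost its EZH2 peak on chromosome 7, from 19116668 to 19117662 with a fold enrichment of 14.8 in sgC, while H3K27me3 was called at an end of the gene in every condition. The gained genes with the highest −log10 q were SNRK, IKZF2, LRP12, COQ2, NR2C2, TTLL7, ITPRID2 and DTX1. SNRK, a kinase gene on chromosome 3, had a peak from 43286247 to 43286582 with a fold enrichment of 11.2, and DTX1, a regulator of Notch signalling, was the member of this group without H3K4me3 in any condition.

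Among the lists fixed before the data were examined, the developmental transcription factors, whose genes are classical PRC2 targets, had EZH2 at 78 of 156 members in sgC DMSO and at 55 in sgPRKCI DMSO, with 14 lost and 0 gained. FOXF1, GATA3, LHX5 and NKX6-2 had the highest −log10 q in sgC, and FOXF1 had the highest in sgPRKCI as well, with fold enrichments of 44.3 and 21.1 within their lists. Both counts stood at percentile 100 of 10000 random lists matched on H3K4me3, whose medians were 28 and 15. Neuroendocrine and neural lineage genes, among them NCAM1, SOX2 and INSM1, had EZH2 at 17 of 38 members in sgC and 11 in sgPRKCI, where random lists had medians of 6 and 4. Basal and mesenchymal genes, led by CAV1 and ZEB2 in sgC, had EZH2 at 10 and 7 of 36 members. The other lists had EZH2 at few members. In sgC, cytosolic ribosomal proteins had 2 of 80 and initiation and elongation factors 1 of 50. Random lists matched on H3K4me3 had medians of 18 and 11, and both counts stood at percentile 0.0. Subunits of oxidative phosphorylation had 9 of 68 in sgC and 0 in sgPRKCI, ribosome biogenesis factors 7 and 1 of 50, mitochondrial ribosomal proteins 6 and 1 of 75, androgen response genes 8 and 2 of 40, and cell cycle genes 6 and 4 of 45. For oxidative phosphorylation, ribosome biogenesis and mitochondrial ribosomal proteins, matched random lists had medians of 15 and 4, 11 and 3, and 17 and 5. Random lists thus fell as well, and these drops are not particular to the lists. Over all genes with H3K4me3, the share with EZH2 was 22.5% in sgC and 7.60% in sgPRKCI. Coverage of the sgPRKCI library was the lower of the pair. With equal numbers of peaks in each EZH2 library, 1030 genes were lost and 288 gained.

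The second comparison, enzalutamide against DMSO in sgC cells, asked what the drug did to EZH2 with PRKCI intact. The EZH2 list was longer on enzalutamide, 15373 against 11452 peaks, yet the number of genes with EZH2 at an end was lower, 2062 against 3657. Of these, 1899 genes lost EZH2, 1852 of them with H3K4me3 in DMSO, and 299 gained it, 186 of them with H3K27me3 on enzalutamide; with equal numbers of EZH2 peaks 1123 were lost and 182 gained. The lost genes with the highest −log10 q were TTC12, MSRA, TMEM19, MTIF3, MAP3K9, KDSR, ZDHHC13 and TP53TG3, each marked by H3K4me3 and not by H3K27me3 in all 4 conditions. MTIF3, an initiation factor of mitochondrial translation, had a DMSO peak on chromosome 13 from 27450067 to 27450538 with a fold enrichment of 6.90. KDSR, an enzyme of ceramide synthesis, had one on chromosome 18 from 63366456 to 63367688 with a fold enrichment of 9.57. The gained genes were TAF11L2, CACNA1E, EMILIN3, ILDR2, MAEL, EBF4, ADRA2C and KCNJ15; ILDR2 and MAEL shared a peak on chromosome 1. CACNA1E, a calcium channel subunit, gained a peak on chromosome 1 from 181317668 to 181319049 with a fold enrichment of 10.3, at a place with H3K27me3 and no H3K4me3 in all 4 conditions. Of these 8 genes, 7 had H3K27me3 in every condition.

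PRC2 target lists had similar EZH2 counts in DMSO and enzalutamide in sgC cells. Developmental transcription factors had 78 and 79 of 156 members with EZH2, 71 of them in both, and FOXF1, GATA3, HOXD8 and SOX14 had the highest −log10 q on enzalutamide. Neuroendocrine genes had 17 and 18 of 38 and basal and mesenchymal genes 10 and 12 of 36. BMI1, which encodes a subunit of Polycomb repressive complex 1, had a peak of fold enrichment 30.7 in DMSO and 59.1 on enzalutamide within their lists. Androgen response genes had 8 and 1 of 40 members with EZH2; MAF was the member with a peak in both, and INSIG1, ACP3 and PMEPA1 were among the 7 lost. EZH2 was called at 0 of 50 ribosome biogenesis factors, 0 of 68 oxidative phosphorylation subunits and 0 of 36 mTORC1 pathway components on enzalutamide, against 7, 9 and 4 in DMSO. Matched random lists had medians of 4, 5 and 2 on enzalutamide and 11, 15 and 8 in DMSO, so they fell as well. Over all genes with H3K4me3, the share with EZH2 fell from 22.5% in DMSO to 8.26% on enzalutamide. The drop at androgen response genes is therefore not shown to be particular to them. Coverage was higher in the enzalutamide library. Outside H3K4me3 peaks, 975 genes had EZH2 on enzalutamide and 794 in DMSO, the opposite order.

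The third comparison, enzalutamide against DMSO in sgPRKCI cells, asked whether EZH2 was redistributed when both were combined. Peaks of this enzalutamide library at H3K4me3 may come from H3K4me3 fragments, as described below, so its counts are counts of peak calls. EZH2 lay at 12553 genes on enzalutamide, 62.6% (62.0 to 63.3) of protein-coding genes, against 1537 in DMSO, with 10949 gained and 65 lost; with equal numbers of EZH2 peaks it lay at 6608 genes on enzalutamide, with 6290 gained. H3K4me3 marked 10747 of the gained genes, and EZH2 was called at 95.8% of all genes with H3K4me3. The gained genes with the highest −log10 q were BRD3OS, GPS1, RFNG, GPAA1, ZDHHC20, EXOSC4, ARFRP1 and ZGPAT. GPS1, a subunit of the COP9 signalosome, and RFNG, a glycosyltransferase acting on Notch, shared a peak on chromosome 17 from 82050382 to 82053390 with a fold enrichment of 112.3, and ARFRP1 and ZGPAT shared a peak on chromosome 20. EXOSC4, a core subunit of the RNA exosome, had a peak on chromosome 8 from 144077390 to 144080044 with a fold enrichment of 52.1. The number of lost genes depended on the setting, with 1247 at equal numbers of EZH2 peaks, 103 where only the 1 kb window of the other library had to be free and 19 at the gene end with H3K4me3 alone. H3K27me3 marked 63 of the 65 lost genes in DMSO, and those with the highest −log10 q were PTPRD, ADAMTS19, COL9A3, DPP6, DTNA, ABCC9, AKAIN1 and CALB2, all with H3K27me3 in every condition and with EZH2 called in the other 3 libraries. PTPRD, a receptor tyrosine phosphatase, had a DMSO peak on chromosome 9 from 10612257 to 10613216 with a fold enrichment of 14.5.

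In sgPRKCI enzalutamide, peaks of the EZH2 library were called at almost all genes of protein synthesis. Summit heights of this library followed H3K4me3, as described below. H3K4me3 fragments in it may therefore account for these calls, and they do not establish EZH2 at these genes. EZH2 was called at 78 of 80 cytosolic ribosomal protein genes, against 1 in sgPRKCI DMSO, with RPS2, RPL8 and RPL7A at fold enrichments of 62.5, 43.6 and 45.7. It was called at all 50 translation initiation and elongation factors, led by EIF2B5, EIF3B, EIF4G1 and EIF3A, and at all 23 cytosolic aminoacyl-tRNA synthetases, led by QARS1, FARSA, GARS1 and KARS1; both lists had 0 in DMSO. Ribosome biogenesis factors, led by UTP4 and BOP1, had 48 of 50, mitochondrial ribosomal proteins, led by MRPL28 and MRPL12, had 73 of 75, mTORC1 pathway components, among them TSC2 and MTOR, had 36 of 36, and ATF4 and amino acid synthesis genes, among them SLC7A1 and PYCR1, had 32 of 33. Other active genes were covered alike: 64 of 68 oxidative phosphorylation subunits such as CYC1, 44 of 45 cell cycle genes such as CDK2 and MKI67, and 38 of 43 Polycomb and chromatin regulator genes such as KMT2D. Beside random lists matched on H3K4me3, the ribosomal proteins stood at percentile 58.1, the initiation and elongation factors at 80.4, the synthetases at 67.6, ribosome biogenesis factors at 72.3, mitochondrial ribosomal proteins at 71.5, oxidative phosphorylation at 73.4, ATF4 and amino acid genes at 68.8, mTORC1 components at 74.2, cell cycle genes at 94.4 and Polycomb regulators at 57.6. Beside unmatched random lists the ribosomal proteins stood at percentile 100, developmental transcription factors at 88.96, neuroendocrine genes at 17.4, basal and mesenchymal genes at 18.99 and androgen response genes at 82.6. The matched percentile was 100 for developmental transcription factors, with 105 of 156 members, for neuroendocrine genes, with 21 of 38, and for basal and mesenchymal genes, with 20 of 36. It was 6.12 for androgen response genes, with 28 of 40 members including CAMKK2 and without ACP3, KLK2 and KLK3, 6.98 for genes of other cell lineages, with 9 of 46, and 0.0 for interferon and antigen presentation genes, with 22 of 48. With equal numbers of peaks in each library, the ribosomal proteins moved to percentile 100 and developmental transcription factors to 0.0.

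**Figure D2:**
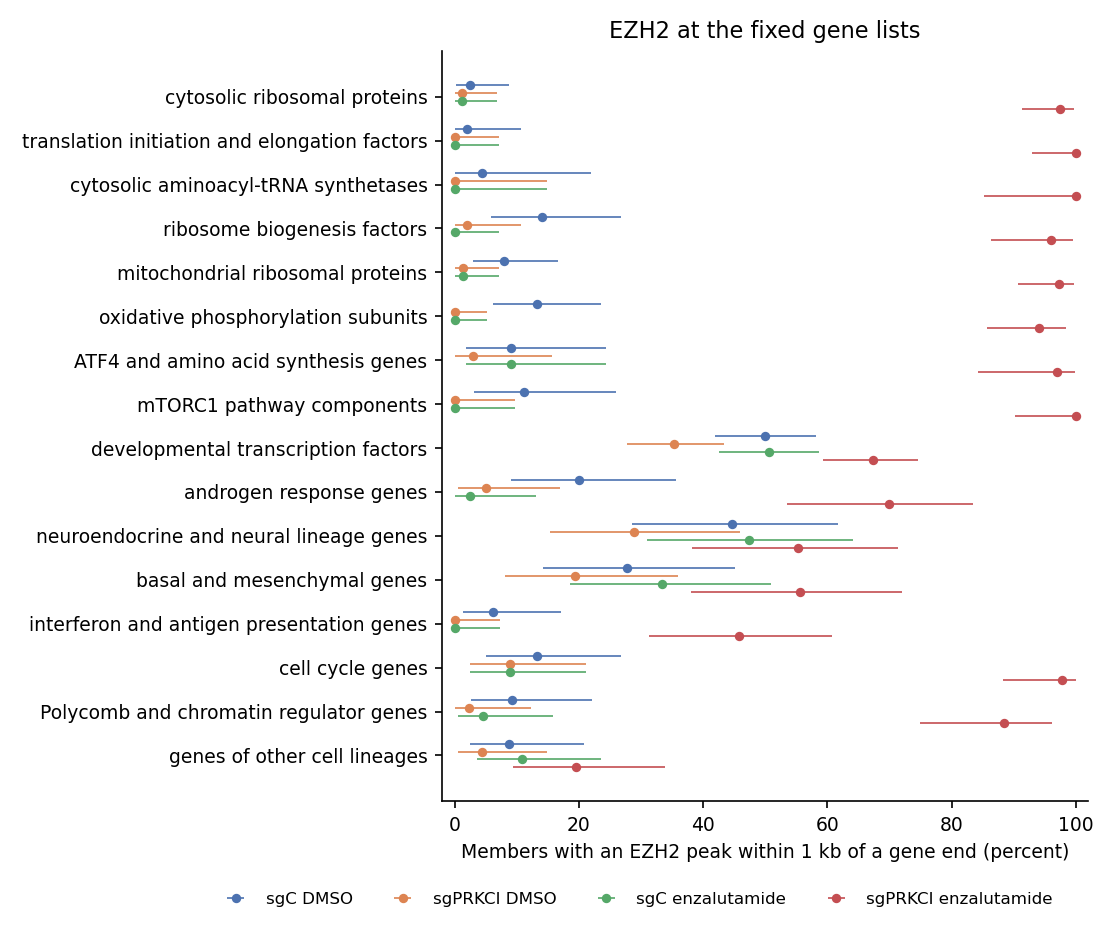
Percent of the members of each fixed gene list with an EZH2 peak within 1 kb of an annotated gene end (horizontal axis), 1 point per library, with exact 95% binomial intervals. In sgPRKCI enzalutamide the ribosomal proteins stand at 97.5% and developmental transcription factors at 67.3%.

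The library of sgPRKCI enzalutamide stood apart from the other EZH2 libraries at these genes. Across the 12964 H3K4me3 sites without H3K27me3 where both were called, its log2 summit heights correlated with those of the H3K4me3 library of the same cells at r = 0.95. The SD of the log2 height ratio was 0.32 there and 0.33 to 0.46 between H3K4me3 libraries, which share more sites. The H3K4me3 libraries correlated with one another at 0.94 to 0.96. The other EZH2 libraries correlated with the H3K4me3 library of their own condition at 0.19, 0.11 and 0.10, over 2643, 673 and 762 sites. Their peaks of the H3K4me3 class had median heights of 15.9, 16.9 and 13.1, against 63.4 in sgPRKCI enzalutamide. Fewer and lower peaks can reduce r and widen summit distances, so these values compare unlike sets. Among those H3K4me3 sites the other EZH2 libraries correlated with one another at 0.70 to 0.76, over 292 to 615 sites. They correlated with the sgPRKCI enzalutamide EZH2 library at 0.19, 0.16 and 0.12, over 2635, 655 and 728 sites. A small number of low peaks therefore did not in itself bring a low r. Sites are not independent replicates. The median distance between EZH2 and H3K4me3 summits was 61 bp in sgPRKCI enzalutamide, 162 bp in sgC DMSO, 145 bp in sgPRKCI DMSO and 174 bp in sgC enzalutamide. With peaks that overlap an H3K4me3 peak of any condition left out, an alternative chosen after the data were seen, EZH2 lay at 822 genes in sgPRKCI enzalutamide and 605 in sgPRKCI DMSO, with 249 gained and 59 lost, and at 0 of the ribosomal protein genes, initiation and elongation factors and synthetases in both.

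**Figure D3:**
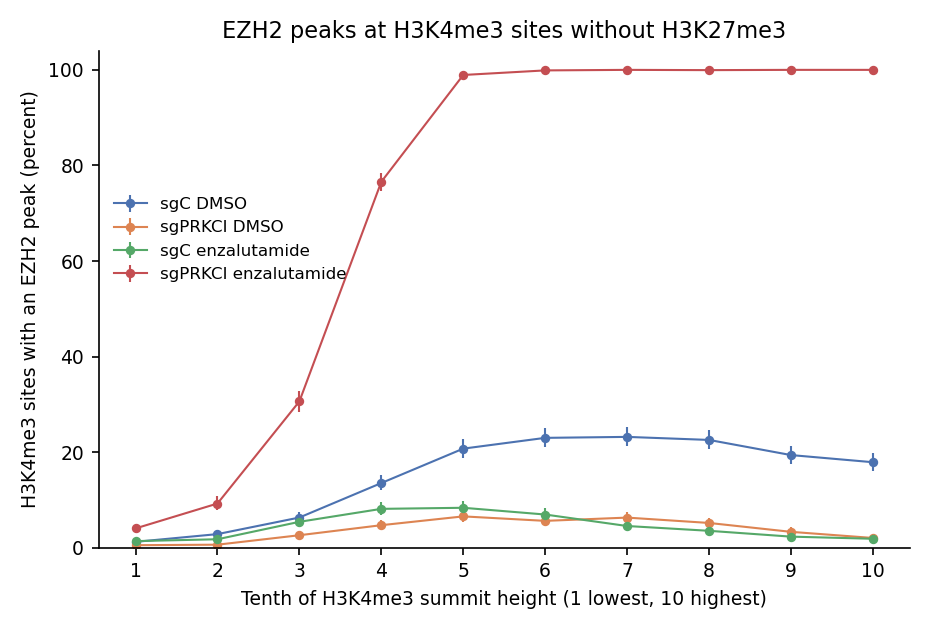
Percent of H3K4me3 sites without H3K27me3 that overlap an EZH2 peak (vertical axis), in 10 groups of rising H3K4me3 summit height in sgPRKCI enzalutamide (horizontal axis), 1 line per EZH2 library with exact 95% binomial intervals. In sgPRKCI enzalutamide the share is 4.06% in group 1 and 100% in group 10; in sgC DMSO it is 23.2% in group 7 and 17.9% in group 10.

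The fourth comparison set sgPRKCI against sgC on enzalutamide. EZH2 lay at 12553 and 2062 genes, with 10667 gained, 10593 of them with H3K4me3, and 257 lost, 245 of them with H3K27me3 in sgC. With equal numbers of EZH2 peaks 6488 were gained and 1285 lost, and at the gene end with H3K4me3 alone 62 were lost and 1071 genes had EZH2 in sgC. Of the 8 gained genes with the highest −log10 q, 7 were also named in the comparison of enzalutamide with DMSO in sgPRKCI cells, BRD3OS, GPS1, RFNG, GPAA1, EXOSC4, ARFRP1 and ZGPAT, and the other was TOR1A, on chromosome 9 from 129822947 to 129824354 with a fold enrichment of 90.2. ZDHHC20, named there, already had EZH2 in sgC on enzalutamide. The lost genes were ABCC9, ADAMTS19, TAF11L12, TAF11L13, TAF11L14, TOX, VEGFC and COL9A3, each with EZH2 in the other 3 libraries and with H3K27me3 in all 4 conditions. VEGFC, a lymphatic growth factor gene, had an sgC enzalutamide peak on chromosome 4 from 176788769 to 176793091 with a fold enrichment of 13.8, and TAF11L13 and TAF11L14 shared a peak in a repeated gene cluster on chromosome 5. The ribosomal protein genes had EZH2 at 78 against 1 of 80 members, the initiation and elongation factors at 50 against 0, and the synthetases at 23 against 0. Developmental transcription factors had 105 against 79, with 33 gained and 3 lost. Outside H3K4me3 peaks the order was the opposite, with 10023 EZH2 peaks in sgPRKCI against 13704 in sgC, 822 against 975 genes, and 116 genes gained and 238 lost. Those peaks covered 7.59 Mb in sgPRKCI and 15.1 Mb in sgC, and 54.0% of the sgPRKCI ones overlapped an sgC one. Coverage was lower in sgPRKCI, 1.53 against 1.68, and lower still for EZH2 if H3K4me3 fragments were mixed in. Lower depth was therefore not told apart from loss of EZH2, here, for the 257 lost genes or for the 65 lost with enzalutamide in sgPRKCI.

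H3K4me3 was called at a similar number of genes in each condition. It lay at 11888 genes in sgC DMSO, 12241 in sgPRKCI DMSO, 12193 in sgC enzalutamide and 12298 in sgPRKCI enzalutamide, between 59.3% and 61.4% of genes, and the base pairs under its peaks overlapped with Jaccard indices of 0.79 to 0.83. All 50 initiation and elongation factors, all 23 synthetases and 79 of 80 ribosomal proteins carried it in every library. Coverage was lowest in the sgC DMSO library, 0.842 against 1.22 in sgPRKCI DMSO and 1.56 in sgC enzalutamide. Gains over sgC DMSO, also those of the lists below, thus ran with depth. In DMSO, sgPRKCI had 355 gained and 51 lost genes against sgC. The gained genes with the highest −log10 q were ZNF844, AHR, the aryl hydrocarbon receptor gene, SHISA8, VIPR2 and SHISA2, and the lost ones MMP16, a membrane-bound matrix metalloproteinase gene, EPHA3, an ephrin receptor gene, PRR29, SELENOV and PLAC9. On enzalutamide, sgPRKCI had 215 gained genes, led by ZNF257, TWIST1, RASAL1, ZNF844 and SHISA6, and 105 lost, led by MMP16, EPHA3, RALYL and the pair LOC124904708 and ZNF540, which shared a peak. MMP16 had a fold enrichment of 30.2 in sgC DMSO and 40.5 in sgC enzalutamide and no peak in either sgPRKCI library. Enzalutamide against DMSO gave 308 gained and 54 lost genes in sgC and 166 and 105 in sgPRKCI. Gained genes were led by TTLL6, SOX18, LGI2, SYT4 and GPC3 in sgC and by TMEM45A, RGPD1, ABCC6, ELFN2 and SEMA5A in sgPRKCI. ST6GALNAC1, a sialyltransferase gene, and CDK3, whose peak was shared with TEN1, led the lost genes of both; PRR29, ACP4 and PCDHGA4 followed in sgC and SYCE2, RGMA and ZDHHC22 in sgPRKCI. The ST6GALNAC1 peak of sgPRKCI DMSO lay on chromosome 17 from 76641578 to 76644100 with a fold enrichment of 35.0. Among the lists, developmental transcription factors had 13 gained and 0 lost in sgPRKCI against sgC in DMSO, 5 and 0 on enzalutamide, and with enzalutamide 11 and 1 in sgC and 3 and 2 in sgPRKCI, and androgen response genes had 30, 31, 29 and 30 of 40 members marked in the 4 conditions.

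H3K27me3 covered 191.7 Mb in sgC DMSO, 232.3 Mb in sgPRKCI DMSO, 289.6 Mb in sgC enzalutamide and 249.3 Mb in sgPRKCI enzalutamide, with mean fold enrichments of 3.37, 3.17, 2.96 and 3.22. Enzalutamide against DMSO gave a ratio of 1.51 in sgC and 1.07 in sgPRKCI, where merging peaks under 3 kb apart turned the difference from 17.0 to -0.71 Mb. Peaks with −log10 q of at least 3 covered 76.9, 104.1, 127.0 and 146.2 Mb, so that on enzalutamide sgPRKCI then had the longer cover, and the ratios were 1.65 and 1.40. Developmental transcription factors carried H3K27me3 at 95, 99, 99 and 94 of 156 members, and neuroendocrine genes at 22, 20, 24 and 22 of 38. In contrast it lay at 0 of 50 initiation and elongation factors, 0 of 23 synthetases and at most 1 of 80 ribosomal proteins in every library. Few genes passed from no peak within 5 kb of either end to at least 5 kb of cover. In DMSO, 10 genes did so in sgPRKCI, led by MMP16, CLCN1, GRIK2, ABCB5 and EPYC, and 2, USP17L1 and USP17L4, which shared a peak, in sgC. On enzalutamide, sgPRKCI had TOX3, MMP16, PPP1R1C, CDH18 and LRRTM4, and sgC had 17 genes, led by FAM90A23, FAM90A14, ITIH5, FAM90A20 and SPTSSB; the FAM90A genes lie in a repeated cluster on chromosome 8. Enzalutamide against DMSO in sgC gave 11 genes, led by EPHA6, PTPRC, LONRF2, C8orf34 and PCDH18, and none in the other direction. In sgPRKCI it gave TOX3, with 2 genes, CDX2, an intestinal homeobox factor whose peak was shared with URAD, and C5AR1, covered in DMSO alone of that pair. The MMP16 end on chromosome 8 that had H3K4me3 in both sgC libraries was covered by H3K27me3 in both sgPRKCI libraries, from 88324074 to 88328974 in DMSO and from 88324032 to 88331268 on enzalutamide.

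**Figure D4:**
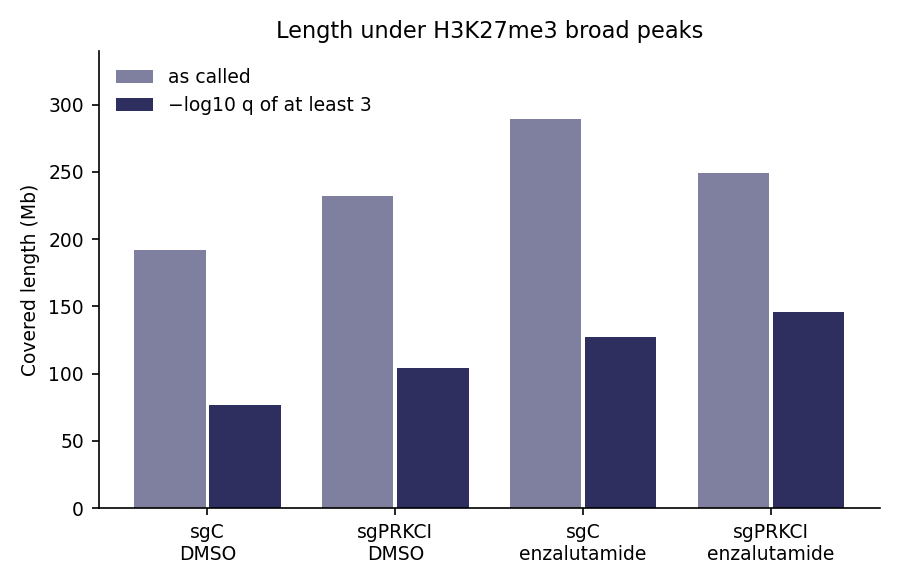
Length in Mb under H3K27me3 broad peaks (vertical axis) in the 4 conditions (horizontal axis), as called and for peaks with −log10 q of at least 3; each bar is 1 library. As called the longest cover is 289.6 Mb in sgC enzalutamide, and at the stricter threshold it is 146.2 Mb in sgPRKCI enzalutamide.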

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

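The tests of library coverage and of height correlation below, the reading of the share of sites over all height groups, the counts over all sites of a list and the values outside H3K4me3 were chosen after the values were seen; the other tests were set before. Results stand here where enzalutamide moved sgC and sgPRKCI cells in opposite directions, or the PRKCI guide moved DMSO and enzalutamide cells in opposite directions; with 1 library each, these differences were not tested.

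With enzalutamide the share of EZH2 peaks at H3K4me3 without H3K27me3 fell by 19.4 percentage points in sgC and was 43.9 points higher in sgPRKCI, a difference of 63.4 points between the effects. The share of EZH2 peaks at H3K27me3 was 21.1 points higher in sgC and fell by 42.5 in sgPRKCI, a difference of -63.6. The number of such peaks was higher with enzalutamide in both, 14270 against 8210 in sgC and 10776 against 5340 in sgPRKCI, so the lower share in sgPRKCI came from the added H3K4me3 class; outside H3K4me3 the share was 2.71 points higher in sgC and 1.36 in sgPRKCI. Genes with EZH2 at an end fell by 1595 in sgC and were 11016 more in sgPRKCI, a difference of 12611; outside H3K4me3 they were 181 and 217 more. EZH2 peaks were 3921 more with enzalutamide in sgC and 18369 more in sgPRKCI, a difference of 14448; against sgC, sgPRKCI had fewer in DMSO, 6182 against 11452, and more on enzalutamide, 24551 against 15373. Outside H3K4me3 they were 5987 and 5239 more, and the difference was -748. Genes with H3K27me3 at an end were 354 more with enzalutamide in sgC and fell by 331 in sgPRKCI, a difference of -685. H3K27me3 length was 97.9 Mb higher with enzalutamide in sgC and 17.0 Mb in sgPRKCI, a difference of -80.9 Mb; against sgC it was higher in sgPRKCI in DMSO and lower on enzalutamide. For peaks with −log10 q of at least 3 the length was 50.03 Mb higher in sgC and 42.1 Mb in sgPRKCI, a difference of -7.92 Mb, and on enzalutamide sgPRKCI had 19.2 Mb more than sgC; with peaks under 3 kb apart merged the value for sgPRKCI was -0.71 Mb.

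The pattern with the largest values is EZH2 at H3K4me3 sites without H3K27me3 in sgPRKCI enzalutamide. Depth is argued against as its cause. This library had a coverage of 1.53, and the sgC enzalutamide library, with 675 such peaks, had 1.68. Preferential recruitment of EZH2 to listed gene groups stays open. At equal H3K4me3 height the furthest list, developmental transcription factors, had a median log2 deviation of -0.0603. Of 13 lists 0 passed the 0.24 found between H3K4me3 libraries, which met the bound set against it, but only sites with an EZH2 peak enter that test. The 0.24 was also the largest of 166 values and came from basal and mesenchymal genes at 10 sites, so passing it was unlikely in advance. Over all sites the lists lay on either side of the number their height gave, as with developmental transcription factors (45 of 53 against 39.98), ribosomal proteins (86 of 103 against 88.42) and neuroendocrine genes (7 of 14 against 8.13). H3K4me3 fragments in this EZH2 library, from a mixed sample or index, may account for the pattern: its heights followed those of H3K4me3 at r = 0.95, as between H3K4me3 libraries (lowest 0.94), at a median log2 ratio of -0.97, and its H3K27me3 peaks would then be the EZH2 part. EZH2 binding in proportion to H3K4me3 in cells with the PRKCI guide on enzalutamide stays open as well and was not tested; a repeat library would separate them.

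The second pattern is the smaller H3K4me3 class of sgC DMSO, 2730 peaks against 712 in sgPRKCI DMSO and 675 in sgC enzalutamide. Lower depth is argued against for enzalutamide, whose library had the higher coverage, 1.68 against 1.35. For the PRKCI guide, weak peaks called only in the deeper library are argued against, since among the 6182 strongest sgC DMSO peaks the share of the class was 22.2%, above the upper bound of 12.3% in sgPRKCI DMSO. Carried-over H3K4me3 fragments met the bound set for them, with EZH2 peaks 14.3 times as frequent in the highest of 10 groups of H3K4me3 height as in the lowest. The later reading gave 23.2% in group 7 and 17.9% in group 10, where carried-over fragments would be the most. Groups were set by H3K4me3 height in sgPRKCI enzalutamide, and calls depend on a local background that was higher at this class. Its peaks had a median fold enrichment of 5.39 at 21.5 fragments, against 6.38 at 17 for H3K27me3 peaks without H3K4me3. The later reading therefore cannot decide. At H3K4me3 sites, EZH2 heights of sgC DMSO followed H3K4me3 of the same condition at r = 0.19, over 2643 sites. They followed the EZH2 libraries of sgPRKCI DMSO and sgC enzalutamide at 0.74 and 0.76, over 531 and 615 sites. The r with H3K4me3 was thus the lower, but low peaks can reduce r and the sets of sites differ. Carried-over fragments therefore stay open. An effect of genotype and drug stays open, untested.

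The third pattern is the longer H3K27me3 cover on enzalutamide in sgC. Weak regions near the calling threshold are argued against as its cause, since the ratio was 1.51 as called and 1.65 for peaks with −log10 q of at least 3. Depth of these libraries is unknown and stays open, as does the drug, untested.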

How the results depend on the processing

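The alternatives that keep only the gene end with H3K4me3 and only EZH2 peaks outside H3K4me3 were chosen after the data were seen; the others before. The start of every annotated transcript was not run, since the gene table gives no strand, and equal numbers fix the count of EZH2 peaks. Of 112 signs of differences between conditions, 105 were kept and 7 were reversed. Of 168 values per library or comparison, 107 stayed within 1.5 times (counts, lengths) or within the interval (shares) and 61 moved; for the latter the cause was not tested unless given. The windows of 500 bp and 2.5 kb, every contig and merging EZH2 peaks moved none of them. Of 624 checks on named gained and lost genes 574 kept the call. Of the other 50, 45 ended when EZH2 peaks at H3K4me3 were left out, by construction, and 5 at 500 bp (NR2C2, PLAC9, SEMA5A, ZDHHC22 and RASAL1). Of 320 list percentiles 279 stayed in the same part of the random lists (under 2.5, over 97.5 or between). Of 320 counts of list members with EZH2, 247 stayed within their interval and 73 moved. Among these were 26 of 64 with equal numbers of EZH2 peaks and 43 of 64 outside H3K4me3. Conditions are given below in the order sgC DMSO, sgPRKCI DMSO, sgC enzalutamide, sgPRKCI enzalutamide.

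With stricter q the H3K4me3 class was 25.8%, 13.6%, 5.50% and 56.7% of EZH2 peaks, the H3K27me3 share 58.6%, 79.0%, 74.9% and 42.3%, and H3K27me3 covered 76.9, 104.1, 127.0 and 146.2 Mb, which turned the difference between sgPRKCI and sgC on enzalutamide from -40.4 to 19.2 Mb. With equal numbers of EZH2 peaks the H3K4me3 class was 22.2% in sgC DMSO, 3.25% in sgC enzalutamide and 98.1% in sgPRKCI enzalutamide, and the H3K27me3 share 74.9%, 95.4% and 1.89% there. Genes with EZH2 were then 2318 in sgC DMSO and 6608 in sgPRKCI enzalutamide, and gained and lost genes 288 and 1030 for sgPRKCI in DMSO, 182 and 1123 for enzalutamide in sgC, 6290 and 1247 for enzalutamide in sgPRKCI, and 6488 and 1285 for sgPRKCI on enzalutamide, fewer peaks being used. With 50% of the peak covered the H3K4me3 class was 12.5% in sgPRKCI DMSO and 4.77% in sgC enzalutamide, and the H3K27me3 share 69.3%, 84.5%, 91.2% and 43.3%. With sgC DMSO marks the H3K27me3 share was 85.3% in sgPRKCI DMSO and 87.3% in sgC enzalutamide, and the H3K4me3 class 54.2% in sgPRKCI enzalutamide. With H3K27me3 peaks merged under 3 kb the H3K27me3 share was 73.2%, 87.4% and 93.9% in the first 3, and the difference in length for enzalutamide in sgPRKCI was -0.71 against 17.0 Mb.

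With no peak asked for in the 1 kb window alone, 103 genes were lost for enzalutamide in sgPRKCI. With the H3K4me3 end alone, genes with EZH2 were 911 in sgPRKCI DMSO and 1071 in sgC enzalutamide, gained genes 153 for enzalutamide in sgC, and lost genes 19 for enzalutamide in sgPRKCI and 62 for sgPRKCI on enzalutamide, fewer genes being counted. Outside H3K4me3, sgPRKCI enzalutamide had 10023 EZH2 peaks, and its difference from sgC was -3681 in place of 9178. The H3K27me3 share was 94.3%, 97.6%, 97.0% and 99.0%, with differences of 1.36 points for enzalutamide in sgPRKCI and 1.92 for sgPRKCI on enzalutamide in place of -42.5 and -48.9. Genes with EZH2 were 794, 605, 975 and 822, with differences of 181 for enzalutamide in sgC and -153 for sgPRKCI on enzalutamide in place of -1595 and 10491. Gained and lost genes were 29 and 188 for sgPRKCI in DMSO, 179 and 56 for enzalutamide in sgC, and gained genes 249 for enzalutamide in sgPRKCI and 116 for sgPRKCI on enzalutamide; peaks at H3K4me3 being left out by construction.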

Other observations

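No tests were planned for the values here; all were chosen after the data were seen. H3K4me3 differences between the genotypes recurred in both treatments, which share no library. Of 355 genes gained in sgPRKCI in DMSO and 215 on enzalutamide, 96 were shared, and of 51 and 105 lost genes 12 were shared. Counts for independent draws here use only genes free of the mark in both references (gained) or marked in both (lost). For H3K4me3, 6764 genes could be gained in both, of which 149 and 183 were, and independent draws would share 4.03; 11790 could be lost in both, of which 33 and 27 were, and draws would share 0.08. These values take no account of genes near the calling threshold, which can flip together, so they are too low by an unknown amount. The shared gained genes, chosen here after their values were seen, included TWIST1 and ERG, transcription factor genes, TGFBR2, a receptor of transforming growth factor beta, BMP2, a bone morphogenetic protein gene, and LOX, a collagen cross-linking enzyme gene. In 65 of the 96, H3K27me3 lay at an end in both sgC libraries, and in none of the 65 was H3K27me3 absent within 5 kb in both sgPRKCI libraries. The shared lost genes included MMP16, EPHA3, RALYL, NFATC2, SEMA6A and NKAIN3, which carried H3K27me3 in both sgPRKCI libraries; 1 of these 6 lacked it within 5 kb in both sgC libraries. H3K27me3 gained in sgPRKCI was shared for 40 genes, against 0.86 for independent draws of 165 and 76 from 14614, and lost for 57, against 4.15 for 99 and 126 from 3007. EZH2 gained in sgPRKCI was shared for 96 genes, against 56.1 for 100 and 8620 from 15353, and lost for 85, against 39.9 for 483 and 139 from 1684. Draws for EZH2, here and for enzalutamide below, were not matched on H3K4me3. Of the 133 genes gained in DMSO 121 carried H3K4me3, and the sgPRKCI enzalutamide library had EZH2 peaks at 95.8% of H3K4me3 genes. Most of the 133 would thus be shared in any case, and the excess of shared gains does not show a recurring effect of the guide. EZH2 coverage was lower in sgPRKCI in both treatments, 1.13 against 1.35 in DMSO and 1.53 against 1.68 on enzalutamide. Shared EZH2 losses thus ran with depth and do not show such an effect either. Coverage of H3K4me3 in sgC DMSO was the lowest of its kind, 0.842, while in enzalutamide sgC had the higher coverage, 1.56 against 1.39.

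Enzalutamide also gave recurring H3K4me3 changes, with coverage higher on the drug in both genotypes, 1.56 against 0.842 in sgC and 1.39 against 1.22 in sgPRKCI, so that shared gains ran with depth. In sgC and sgPRKCI, 308 and 166 genes gained the mark and 51 were shared, against 2.06 for independent draws of 101 and 137 from 6719; NKX2-1, OLIG2 and LBX1, homeobox and helix-loop-helix factors of neural and foregut development, HOXC10 and CTCFL were among them. Of 54 and 105 lost genes 11 were shared, against 0.07 for 33 and 26 from 11798, including ST6GALNAC1, CDK3, C3 and TLE4. For EZH2, 164 of 299 and 10949 gained genes were shared, against 147.6 for independent draws of 265 and 8711 from 15637, and 4 of 1899 and 65 lost genes, against 9.87 for 240 and 57 from 1386.

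A core of EZH2 genes was common to the 4 libraries. EZH2 lay at 1056 genes in all of them, 51 of them developmental transcription factors, and 876 of the 1056 also had H3K27me3 in all 4 conditions.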
